A study of Mus musculus with 8 samples.

How the data were processed

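Total RNA was taken from mouse embryonic fibroblasts of Daxx knockout animals (FVB/N background) that had been complemented with a vector or with Daxx, and was amplified, biotin-labelled and hybridised to Affymetrix mouse gene arrays, per the labels' protocols. The 8 samples formed 2 conditions by their source names, vector (4 arrays) and Daxx (4 arrays), and 3 groups by their titles, vector (4), DaxxA (2) and DaxxB (2). The labels do not say what A and B stand for, nor whether the samples of a group came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

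The deposited values are log2 signals made with Affymetrix Expression Console and the RMA method, per the submitters' processing notes. RMA subtracts a background from the probe intensities, sets the arrays to a common distribution by quantile normalization and combines the probes of a probe set into 1 log2 value. It compresses small differences near the background and hides a change shared by most genes. Software versions, library file and genome build are not given in the sources used here. No detection calls are given, so weak signals were not removed in the main analysis. The number of arrays limits the precision, and self-tests gave its size.

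The table held 35556 probe sets in 8 columns, each of which matched 1 sample. Gene symbols came from the platform's probe annotation: 21789 probe sets had 1 gene symbol, 1621 had several and 12146 had none listed. Probe sets with several symbols or none were left out of the gene counts. Where a gene had more than 1 probe set, the one with the highest mean over the 8 arrays was used, which set aside 1850 probe sets and left 19939 genes. Of these, 19856 were matched by gene number to a reference table of the GRCm38.p6 assembly, and 0 symbols needed an update. That table served for names and for which genes neighbour each other, and no coordinates are given because the build of the array annotation is not named.

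Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the deposited log2 values, with Benjamini-Hochberg adjustment over all genes. Genes with an adjusted p below 0.05 were called, and those with an absolute log2 change of at least 1 were called 2-fold. Daxx against vector used 2 conditions over all 8 arrays. DaxxA, DaxxB and their difference used a fit of 3 groups with 1 shared estimate of spread. The Daxx probe set was also tested with an exact two-sided permutation test. Overlap between DaxxA and DaxxB, which share the vector arrays, was set beside 20 simulations of unchanged groups against those arrays, beside the overlap of independent lists, and beside the 6 ways of dividing the vector arrays 2 and 2.

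The 35 gene lists (24 of pathways and 11 of cell markers, with 754 entries of which 679 were matched to a measured gene) were fixed before the data were examined, as were the main tests, the rules for naming genes and most alternatives. They covered Daxx partners and PML bodies, neighbours of the Daxx locus, NF-kB targets, interferon-stimulated genes, MHC class I, p53 targets, apoptosis, autophagy and lysosome, cholesterol, fatty acids, collagens and matrix, matrix proteases, TGF-beta and contractile genes, cell cycle, DNA replication, glycolysis and hypoxia, the unfolded protein response, NRF2, heat shock, imprinted genes, germline genes, Hox genes, the Wnt pathway and ribosomal proteins. The marker lists were for fibroblasts, epithelium, endothelium, blood cells, smooth muscle and pericytes, skeletal muscle, adipocytes, cartilage and bone, neural cells, pluripotency and the sex chromosomes. They were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 35 lists, with an estimated correlation and limma's fry beside it. Fry tests whether the members of a list move one way on balance, or, in its mixed form, in either direction. List entries with no match, 74 distinct genes, were not analysed here.

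The named genes were Daxx, the 12 with the highest and the 12 with the lowest change among called genes whose 4 Daxx values all lay on one side of the 4 vector values, up to 4 members of each list by adjusted p, and the 5 highest and 5 lowest for DaxxA against DaxxB. Predicted genes, olfactory receptors, small RNAs and antigen receptor segments were skipped. The DaxxA against DaxxB genes could be named only from the fit without vector replicate 2, since 0 were called with all 8 arrays.

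The fits were tested on simulated data with the means and spread of the real 19939 genes and 200 genes changed. For Daxx minus vector with 8 arrays 60% of genes changed by 0.5 and 90% of those changed by 1 on the log2 scale were recovered, and 6.25% of the calls were false. For 7 arrays without vector replicate 2 the shares were 94%, 99% and 4.46%. The simulated list shifted by 0.3 was called and 0 unshifted lists were. The simulated genes varied independently, with the same spread in every array. The self-test therefore cannot show how often lists are called falsely when genes vary together, and its shares of recovered genes assume no array that stands apart.

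Alternatives were quantile normalization, median centring, cyclic loess, a filter on genes above the median level, a trended and robust prior, array weights, leaving out each array, the replicate number as a block, other choices of probe set, a mean over DaxxA and DaxxB in the fit of 3 groups, and the group as a random block. Combined settings on 7 arrays, the lists between DaxxA and DaxxB, and families by symbol prefix were added after the data were seen. Results of other splits of the samples count each division of the 8 arrays into 4 and 4, or of the 7 arrays into 3 and 4, once (35 of each).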

Results

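Daxx is a histone chaperone and transcriptional regulator that deposits the histone variant H3.3 together with Atrx and resides in PML nuclear bodies. The data were 8 expression arrays of mouse embryonic fibroblasts from Daxx knockout animals of the FVB/N background. In 4 samples the cells carried an empty vector, and in 4 samples Daxx had been put back. The Daxx samples bore 2 names, DaxxA (2 samples) and DaxxB (2 samples), whose meaning the labels do not give. Each array gave log2 signals for 35556 probe sets, from which 1 probe set was taken for each of 19939 genes. The question was which genes are regulated downstream of Daxx. Values are log2 signals, and changes are Daxx minus vector with a standard error (SE) unless stated otherwise, over 4 arrays against 4.

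One array stood apart. The interquartile range of vector replicate 2 was 2.79, and that of the other 7 arrays lay between 3.31 and 3.39. Its mean correlation with the other arrays across probe sets was 0.969, whereas the other 7 correlated with each other at 0.991 to 0.998. Its median over 1027 olfactory receptor genes, which fibroblasts are not known to use, was 5.21, against 4.65 to 4.70 in the other arrays. No 2 arrays held identical columns. All 8 arrays entered the comparisons, and values on 7 arrays, without vector replicate 2, are given beside the main counts. That choice was made after the data were seen.

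**Figure D1:**
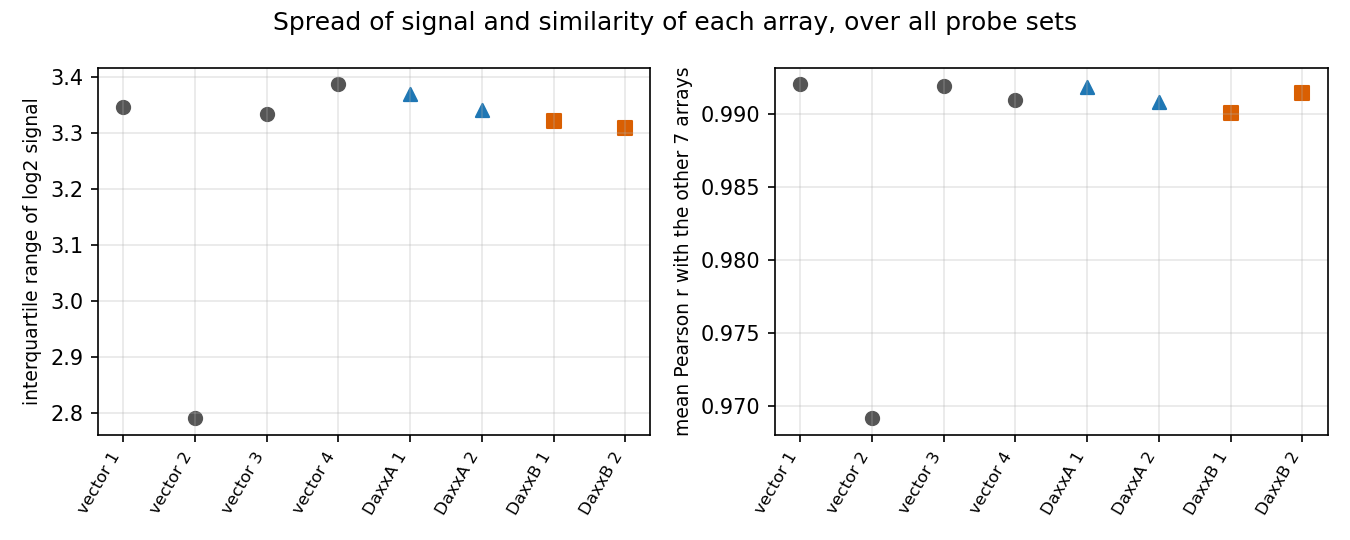
Each point is 1 array, with the interquartile range of its log2 signals on the left and its mean Pearson correlation with the other 7 arrays on the right. Vector replicate 2 lies at 2.79 and 0.969, below the other 7 arrays on both axes.

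The Daxx probe set was examined first. It read 7.15 ± 0.216 (SD, n = 4) in the vector arrays and 7.35 ± 0.0964 (SD, n = 4) in the Daxx arrays. The difference of 0.20 had a 95% interval from -0.05 to 0.44, which corresponds to at most 1.36-fold. An exact two-sided permutation test gave p = 0.143, where the smallest p that 4 against 4 arrays allow is 0.0286. On 7 arrays, without vector replicate 2, the difference was 0.10 with an exact permutation p of 0.229. The vector mean lay above 99.2% of the olfactory receptor genes. This signal therefore did not separate the conditions, and where its probes lie relative to the deleted part of the gene or to the sequence put back is not given in the sources used here. All directions below rest on the labels, and the samples are named as the arrays labelled Daxx or vector.

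The first comparison asked which genes differed between the arrays labelled Daxx and vector. The strongest change was in Sfrp1, a secreted Wnt antagonist, which fell by 3.0 on the log2 scale (SE 0.074, 8.0-fold, adjusted p = 5.83e-07, n = 4 and 4), from 12.1 to 9.11. Mme, the membrane endopeptidase neprilysin, fell 3.61-fold. Grem1, a secreted antagonist of bone morphogenetic proteins, fell 3.46-fold. Cd34, a sialomucin of progenitor and stromal cells, fell 3.4-fold. The main increases were in Plxdc2, a plexin domain protein of the cell surface (2.81-fold), Gsta4, a glutathione transferase that conjugates lipid peroxidation products (2.31-fold), and Gfra2, a co-receptor for neurturin (2.28-fold).

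Another 8 genes completed the list of 12 with the lowest values. Saa3, an acute phase serum amyloid protein, fell by 1.67 on the log2 scale (SE 0.132), and Rspo2, a secreted activator of Wnt signalling, fell by 1.63 (SE 0.114). Gpc4, a heparan sulfate proteoglycan, fell by 1.63 (SE 0.084). Svep1, a large matrix protein, fell by 1.60 (SE 0.154), and Gria3, a glutamate receptor subunit, fell by 1.60 (SE 0.079). Rasl11a, a small GTPase-like protein, fell by 1.56 (SE 0.064), Cemip, a hyaluronan-degrading protein, by 1.54 (SE 0.077), and Dcn, the proteoglycan decorin, by 1.47 (SE 0.094). Adjusted p-values of these 8 genes ran from 2.02e-05 to 0.000593. Svep1 read 8.86 in vector replicate 2 and 9.38 on average in the vector arrays.

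Smaller increases completed the list of 12 genes with the highest values. Parvb, an adaptor of integrin adhesions, rose 2.04-fold (adjusted p = 0.000867), and Pdgfb, a platelet-derived growth factor chain, rose 2.01-fold (adjusted p = 0.00114). Nid1, the basement membrane protein nidogen, rose 2.0-fold (adjusted p = 0.0195). Pcolce2, an enhancer of procollagen processing, rose 1.97-fold and Tagln, an actin-binding protein of contractile cells, rose 1.97-fold. Mpp1, a scaffold protein of the membrane skeleton, rose 1.96-fold with the smallest spread of these (SE 0.049, adjusted p = 2.02e-05). Sh3bgrl2 rose 1.86-fold and Tnfaip2, a gene induced by tumour necrosis factor, rose 1.84-fold. Prl2c5 rose 1.90-fold (adjusted p = 0.0254), and because it belongs to a family of near-identical prolactin genes its identity on this array is uncertain. Vector replicate 2 gave the lowest of the 4 vector values for Plxdc2 (7.06) and Nid1 (7.76). Without it Plxdc2 rose by 1.22 rather than 1.49 on the log2 scale, and Nid1 by 0.79 rather than 1.00.

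**Figure D2:**
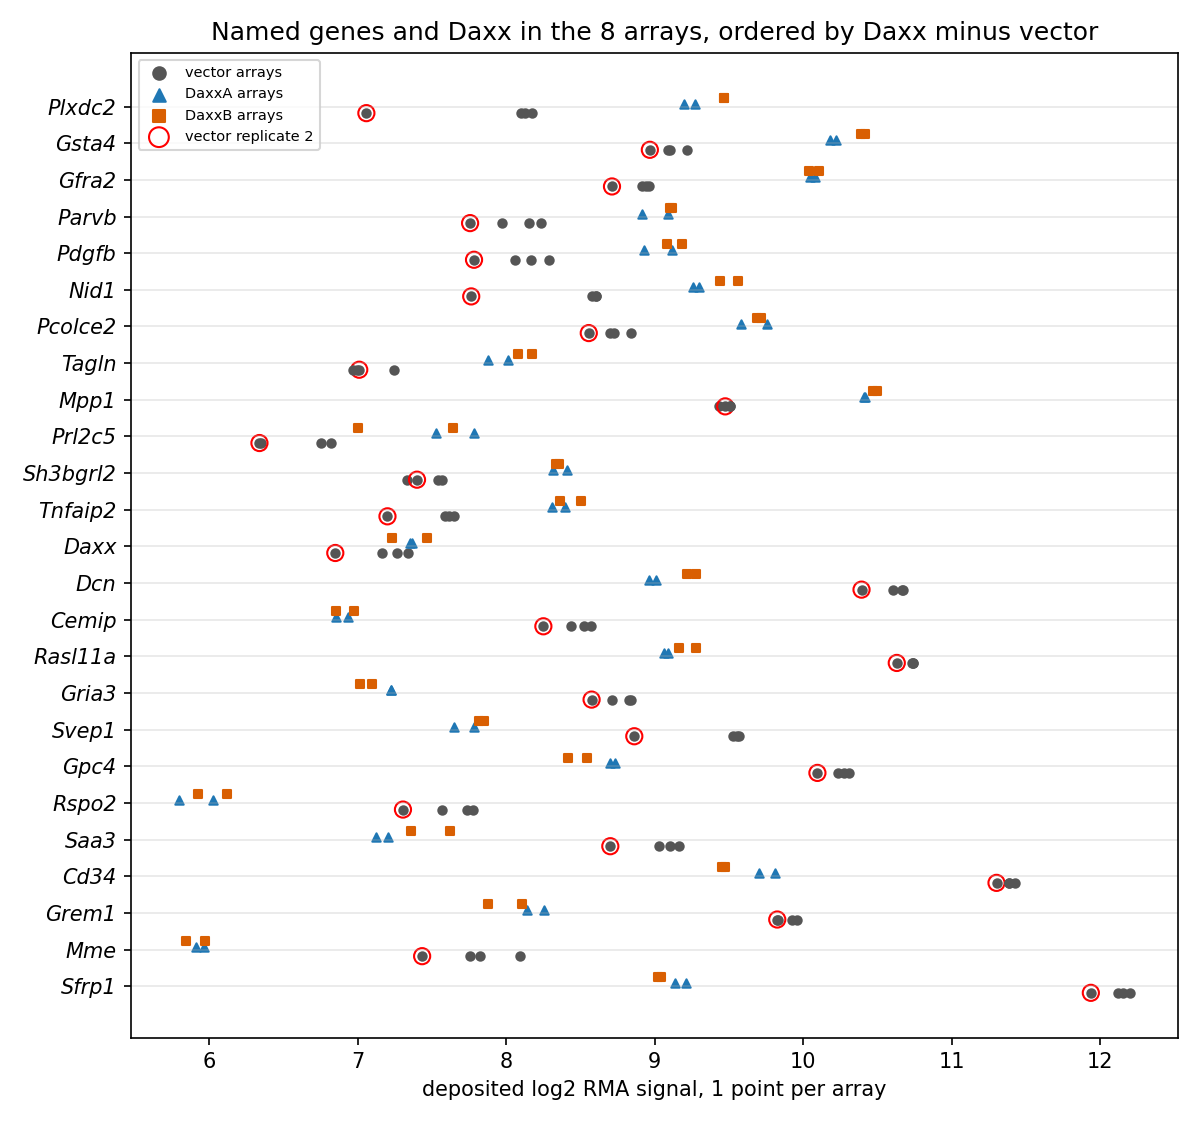
Each point is the deposited log2 signal of a gene in 1 array, with vector, DaxxA and DaxxB arrays in different colours and vector replicate 2 ringed. For the 24 named genes the 4 Daxx values lay on one side of the 4 vector values, and for Daxx they overlapped.

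Across the 19939 genes, 902 passed an adjusted p of 0.05 in limma (4.52%), of which 358 rose and 544 fell. At least 2-fold changes numbered 54, of which 6 rose and 48 fell. In all 902 genes the 4 Daxx values lay entirely above or below the 4 vector values. Such a separation held for 14.8% of all genes, where chance gives 2.86%. Leaving out vector replicate 2 gave 2558 genes (1048 rose, 1510 fell), with 62 at 2-fold, of which 3 rose and 59 fell. All 902 genes were called there too with the same direction, and 50 of the 54 at 2-fold. The number of called genes depended on single arrays: it was 483 without vector replicate 1, 457 without vector replicate 3 and 559 without vector replicate 4, 478 and 514 without DaxxA replicate 1 or 2, and 504 and 446 without DaxxB replicate 1 or 2.

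Gene lists fixed before the data were examined were then compared as groups. Of 35 lists, camera called 11, of which 5 were lower and 6 higher in the Daxx arrays. With an estimated correlation between genes 1 list was called, the interferon-stimulated genes. The estimate for that list was below 0 (-0.0263, and -0.00477 without vector replicate 2), so the setting made no allowance for its members varying together. Its adjusted p still rose from 5.95e-11 to 0.0075. The loss of lists under this setting therefore cannot be put down to genes varying together alone. For the other called lists the estimate on 8 arrays ran from 0.0476 (Hox genes) to 0.483 (unfolded protein response and ATF4 targets). The preset correlation gave 10 called lists without vector replicate 2, of which 6 were among the 11. A count of 11 was not rare: 16 of the 35 splits of the 8 arrays into 4 and 4 called at least as many lists, up to 18. On 7 arrays the real split called 10 and no other split more than 9. For single lists on 8 arrays, the splits with a camera p as small included the real one. They numbered 27 of 35 for the unfolded protein response, 11 for p53 targets, 6 for neighbours of the Daxx locus and 6 for ribosomal proteins. For MHC class I they numbered 5, for NRF2 4, for NF-kB targets 3, and for glycolysis and hypoxia 2. Interferon-stimulated genes, Hox genes and fibroblast markers had 1 each.

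Interferon-stimulated genes had the clearest shift. None of the 27 measured members had a value above 0, 11 fell and 16 did not pass, and 15 fell when adjusted over the list alone (median -0.29, camera adjusted p = 5.95e-11; adjusted p = 0.0075 with an estimated correlation). Ifit1, which binds foreign RNA, fell 2.22-fold (SE 0.14), Gbp7, a guanylate-binding protein, fell 2.0-fold (SE 0.096), Irf9, a subunit of the interferon transcription factor, fell 1.43-fold and Xaf1, a proapoptotic interferon target, fell 1.32-fold. On 7 arrays, without vector replicate 2, 23 members had a value below 0 and 4 above, 15 fell, and the adjusted p was 3.81e-12, or adjusted p = 0.0142 with an estimated correlation.

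Hox genes, which set position along the body axis, were lower too. Of 33 measured members 7 fell, 0 rose and 26 did not pass, and 14 fell and 1 rose when adjusted over the list alone (median -0.20, camera adjusted p = 1.24e-06; adjusted p = 0.14 with an estimated correlation). Hoxb13 fell 1.92-fold, Hoxc8 1.57-fold, Hoxb5 1.47-fold and Hoxb9 1.42-fold. The mean of the list was 7.29 in vector replicate 2 and 7.12 to 7.16 in the other vector arrays, above the 6.91 to 6.95 of the Daxx arrays. With that array left out 15 members fell and 1 rose. Camera then gave an adjusted p of 1.42e-06, and the adjusted p was 0.121 with an estimated correlation.

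Fibroblast markers went both ways with more members lower. Of 17 measured members 5 fell, 2 rose and 10 did not pass, and 8 fell and 2 rose when adjusted over the list alone (median -0.26, camera adjusted p = 0.00518; adjusted p = 0.476 with an estimated correlation). Prrx1, a transcription factor of limb and craniofacial mesenchyme, fell 2.10-fold, Pdgfrb, the receptor for platelet-derived growth factor, fell 1.62-fold and Twist2, a mesenchymal transcription factor, fell 1.34-fold. Without vector replicate 2 the median was -0.042 and the adjusted p was 0.00369, or adjusted p = 0.431 with an estimated correlation. NF-kB targets, largely cytokine and adhesion genes, had 6 members lower, 0 higher and 19 not passing of 25, and 10 lower and 3 higher when adjusted over the list alone (median -0.14, camera adjusted p = 0.00518; adjusted p = 0.491 with an estimated correlation). Vcam1, a leukocyte adhesion molecule, fell 1.72-fold, Cxcl5, a neutrophil chemokine, 1.88-fold, Ccl5, a T cell chemokine, 1.5-fold, and Il6, an inflammatory cytokine, 1.32-fold. On 7 arrays 9 members of that list were lower and 3 higher (adjusted p = 0.00151; adjusted p = 0.431 with an estimated correlation). Genes of MHC class I and antigen processing numbered 13, of which 3 fell, 1 rose and 9 did not pass, with the same 3 and 1 when adjusted over the list alone (median -0.11, camera adjusted p = 0.0284; adjusted p = 0.491 with an estimated correlation). The peptide transporter genes Tap1 and Tap2 fell 1.29-fold and 1.18-fold and the immunoproteasome gene Psmb8 fell 1.38-fold, while H2-M3, a nonclassical class I gene, rose 1.40-fold. On 7 arrays 5 members fell and 1 rose, or 8 and 1 when adjusted over the list alone (adjusted p = 0.00183; adjusted p = 0.201 with an estimated correlation).

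The lists that were higher had few called members. Glycolysis and hypoxia genes had 3 of 23 members higher, 0 lower and 20 not passing, and 5 higher when adjusted over the list alone (median 0.09, camera adjusted p = 0.000416; adjusted p = 0.491 with an estimated correlation). Pfkp, a phosphofructokinase of glycolysis, rose 1.51-fold, Slc16a3, a lactate exporter, 1.29-fold, and Vegfa, an angiogenic factor, 1.22-fold. The list mean was 9.29 in vector replicate 2, 9.37 to 9.42 in the other vector arrays and 9.46 to 9.52 in the Daxx arrays. The call held without vector replicate 2, where 6 members rose and 0 fell (camera adjusted p = 0.0208, or adjusted p = 0.431 with an estimated correlation). Unfolded protein response and ATF4 targets had 2 of 24 members higher and 22 not passing, also 2 when adjusted over the list alone (camera adjusted p = 0.00885; adjusted p = 0.707 with an estimated correlation), Atf4 itself (1.34-fold), a stress transcription factor, and Mthfd2, a mitochondrial folate enzyme (1.29-fold). NRF2 and antioxidant genes had 2 higher, 1 lower and 16 not passing of 19, with 3 and 1 when adjusted over the list alone (camera adjusted p = 0.00885; adjusted p = 0.491 with an estimated correlation). Those were Gsta4, Aox1, an aldehyde oxidase (1.28-fold), and Mgst1, a microsomal glutathione transferase, which fell 1.44-fold. Without vector replicate 2 these last 2 lists were not called (camera adjusted p = 0.279 and 0.0803). Their single members called there were 3 higher and 2 lower for the unfolded protein response, and 5 higher and 1 lower for NRF2.

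The remaining 3 called lists were each lost without vector replicate 2. p53 targets had 2 higher, 1 lower and 19 not passing of 22, and 6 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.0439, or adjusted p = 0.598 with an estimated correlation). Without that array 6 members rose and 3 fell, and the camera adjusted p was 0.199. Trp53inp1, a stress-induced p53 target, rose 1.45-fold, Ccng1, a cyclin G, rose 1.17-fold and Sesn1, a stress sensor, fell 1.21-fold. Genes near the Daxx locus had 0 of 11 members called, 0 adjusted over the list alone (median 0.09, camera adjusted p = 0.0245; adjusted p = 0.499 with an estimated correlation; 0.308 without that array, where 1 fell). Ribosomal protein genes had 0 of 23 called, 0 adjusted over the list alone (median 0.05, camera adjusted p = 0.0284; adjusted p = 0.499 with an estimated correlation; 0.209 without that array, where 1 rose).

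**Figure D3:**
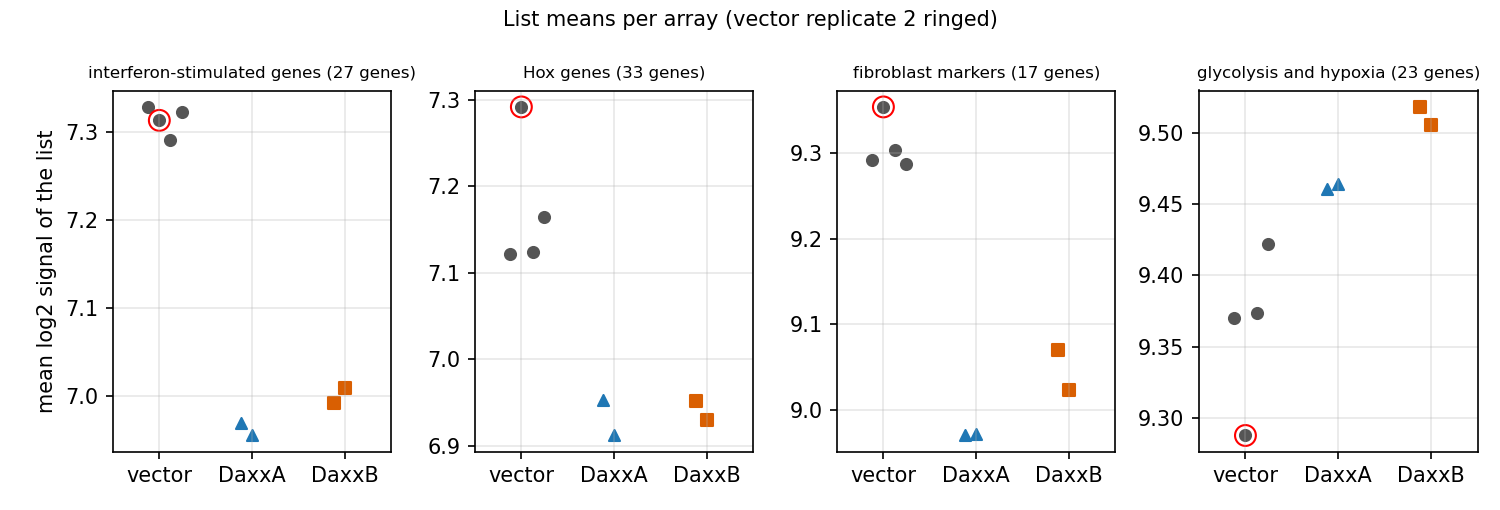
Each point is the mean log2 signal of 1 gene list in 1 array, for the interferon-stimulated genes, Hox genes, fibroblast markers, and glycolysis and hypoxia genes, with vector replicate 2 ringed. The interferon list lies between 7.29 and 7.33 in the vector arrays and between 6.95 and 7.01 in the Daxx arrays.

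The other 24 lists were not called by camera on 8 arrays, although many held single changed genes. Fry in its form for one direction called 3 of them, all lower: the Wnt list (adjusted p = 0.00273), matrix proteases and inhibitors (0.0202) and imprinted genes (0.0202). Its mixed form, for changes in either direction, also called lists such as Daxx partners (adjusted p = 0.00377), collagens (3.44e-07), autophagy (2.78e-06), apoptosis (7.81e-06) and cell cycle (7.81e-06). It did not call others, such as cholesterol (0.119), fatty acid (0.179) and germline genes (0.191). Camera with an estimated correlation gave these lists adjusted p-values of 0.499, 0.707 and 0.491. The medians of 2 of these 3 lists changed sign without vector replicate 2, from -0.101 to 0.00973 for the Wnt list and from -0.0758 to 0.0248 for imprinted genes, each with 12 members above 0 and 10 below. Their means stayed below 0 there (-0.262 and -0.0796), and fry still called both lower (adjusted p = 0.00464 and 0.0459). Among collagens and matrix genes 6 of 34 fell and 2 rose (7 and 4 when adjusted over the list alone, camera adjusted p = 0.6), including Fbln5, an elastic fibre protein (2.73-fold lower), Thbs2, a matricellular thrombospondin (1.56-fold lower), and Lox, the crosslinking lysyl oxidase (1.54-fold lower). Leaving out vector replicate 2 gave 12 lower and 5 higher in this list, which was still not called (camera adjusted p = 0.0803). Matrix proteases and inhibitors had 5 of 19 lower and 4 higher (8 and 5 when adjusted over the list alone, adjusted p = 0.174): the aggrecanases Adamts5 and Adamts1 fell 2.39-fold and 2.30-fold, the protease inhibitor Timp3 fell 1.44-fold and Timp1 rose 1.45-fold. Without vector replicate 2 this list was called lower (adjusted p = 0.0235; adjusted p = 0.431 with an estimated correlation). TGF-beta and contractile genes had 3 of 22 higher and 3 lower (5 and 3 when adjusted over the list alone, adjusted p = 0.234), with Acta2, smooth muscle actin, 1.31-fold higher and Thbs1, thrombospondin, 1.8-fold lower. Wnt pathway targets and antagonists had 5 of 22 lower and 1 higher (5 and 2 when adjusted over the list alone, adjusted p = 0.0972), with Rnf43, a ubiquitin ligase for Wnt receptors, 2.11-fold lower and Wnt5a, a Wnt ligand, 2.02-fold lower. Imprinted genes had 4 of 22 lower and 1 higher (5 and 2 when adjusted over the list alone, adjusted p = 0.174), with the growth factor Igf2 1.99-fold lower and Plagl1, a zinc finger regulator, 1.39-fold lower.

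Few members were called in the lists of Daxx partners and general cell functions. Of the 21 measured Daxx partners and PML body genes 0 were called, also when adjusted over the list alone (median -0.02, camera adjusted p = 0.826). Without vector replicate 2, 3 of them fell, the histone chaperone genes Asf1b (adjusted p = 0.0093) and Ubn1 (0.0153) and Pml, the scaffold of the bodies (0.0314), and the list was not called (camera adjusted p = 0.239). Apoptosis regulators had 2 of 32 higher and 1 lower, with the same counts when adjusted over the list alone (adjusted p = 0.432): the survival gene Bcl2 rose 1.30-fold, the initiator caspase Casp8 rose 1.30-fold and Casp12 fell 1.41-fold. In this list 3 rose and 4 fell without vector replicate 2 (camera adjusted p = 0.601). Autophagy and lysosome genes had 1 of 33 higher, Sqstm1, an autophagy receptor (1 when adjusted over the list alone, camera adjusted p = 0.826). Without vector replicate 2, 7 of them fell and 2 rose, and the list was called lower (adjusted p = 0.0404, or adjusted p = 0.37 with an estimated correlation). Cell cycle genes had 1 of 27 lower, the spindle motor Kif11 (1 when adjusted over the list alone, camera adjusted p = 0.408). With vector replicate 2 left out 4 fell and 0 rose, and this list was also called lower (adjusted p = 0.0235, or adjusted p = 0.431 with an estimated correlation). Cholesterol genes had 1 of 20 higher (1 when adjusted over the list alone, adjusted p = 0.432, median -0.01 and mean 0.03), DNA replication genes 1 of 28 higher (0 when adjusted over the list alone, adjusted p = 0.289), and fatty acid genes 0 of 21 (0 when adjusted over the list alone, adjusted p = 0.743; 1 lower without vector replicate 2). Heat shock genes had 1 of 11 higher, the chaperone Hspb8 at 1.59-fold (1 higher and 1 lower when adjusted over the list alone, adjusted p = 0.455), with a median just below 0 and a mean above 0. Germline genes had 1 of 20 lower, Tdrkh (1 when adjusted over the list alone, adjusted p = 0.199).

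Markers of other cell types gave no called list on 8 arrays. Smooth muscle and pericyte markers had 2 of 11 higher, Smtn and Mcam (2 when adjusted over the list alone, adjusted p = 0.131), and were called higher without vector replicate 2 (adjusted p = 0.0235; adjusted p = 0.431 with an estimated correlation). Neural markers had 2 of 12 higher and 1 lower (3 and 1 when adjusted over the list alone, adjusted p = 0.442), with the intermediate filament gene Nes and the neuronal microtubule gene Map2 1.41-fold and 1.51-fold higher and Sox2, a stem cell transcription factor, 1.56-fold lower. Adipocyte markers had 1 of 9 lower, Pparg (1 when adjusted over the list alone, adjusted p = 0.198), and pluripotency markers 1 of 10 lower, again Sox2 (1 when adjusted over the list alone, adjusted p = 0.131). Epithelial (15 genes, adjusted p = 0.706), endothelial (12 genes, 0.432), blood cell (13 genes, 0.743) and skeletal muscle markers (13 genes, 0.561) had 0 called members, also when adjusted over the list alone and on 7 arrays. Cartilage and bone markers had 0 of 11 called, and 1 higher when adjusted over the list alone or on 7 arrays (adjusted p = 0.944, with a median below 0 and a test direction above 0). Of 4 sex chromosome genes 1 fell, Xist, the RNA that coats the inactive X chromosome, which was 1.86-fold lower (1 when adjusted over the list alone, adjusted p = 0.154).

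The second comparison took DaxxA and DaxxB apart and asked whether each differed from the vector arrays in the same way. The log2 change of Sfrp1 was -2.93 in DaxxA and -3.07 in DaxxB, that of Mme -1.84 and -1.87, and that of Grem1 -1.68 and -1.89. Gfra2 rose by 1.18 and 1.19, and Plxdc2 by 1.37 and 1.60. In DaxxA 393 genes passed (104 rose, 289 fell), and in DaxxB 536 (153 rose, 383 fell). Leaving out vector replicate 2 raised these counts to 2246 (890 rose, 1356 fell) and 4083 (2182 rose, 1901 fell), so that in DaxxB the higher genes then outnumbered the lower ones. The median change of all genes was then -0.00835 in DaxxA and 0.0357 in DaxxB. The 2 sets shared 316 genes with the same direction (76 higher, 240 lower) and 0 with opposite directions, where independent lists would share 0.798 higher and 5.55 lower. On 7 arrays, without vector replicate 2, they shared 1678 with the same direction and 3 with opposite directions.

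Both sets were compared with the same vector arrays, so part of this overlap may be shared noise. Across genes, which are not independent replicates, the changes correlated at r = 0.802, and 0.334 in simulated unchanged groups, with a covariance of 0.029 against a simulated 0.0063, a difference of 0.0227. When the vector arrays were divided 2 and 2 between DaxxA and DaxxB, so that no array was shared and the simulated values do not apply, r was 0.249 to 0.501 and the covariance 0.0126 to 0.0206 over the 6 divisions. Simulated unchanged groups shared at most 0 called genes. These simulations drew independent noise of the same spread in every array, so a count near 0 was fixed in advance. They do not measure noise that vector replicate 2 carries into both sets.

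**Figure D4:**
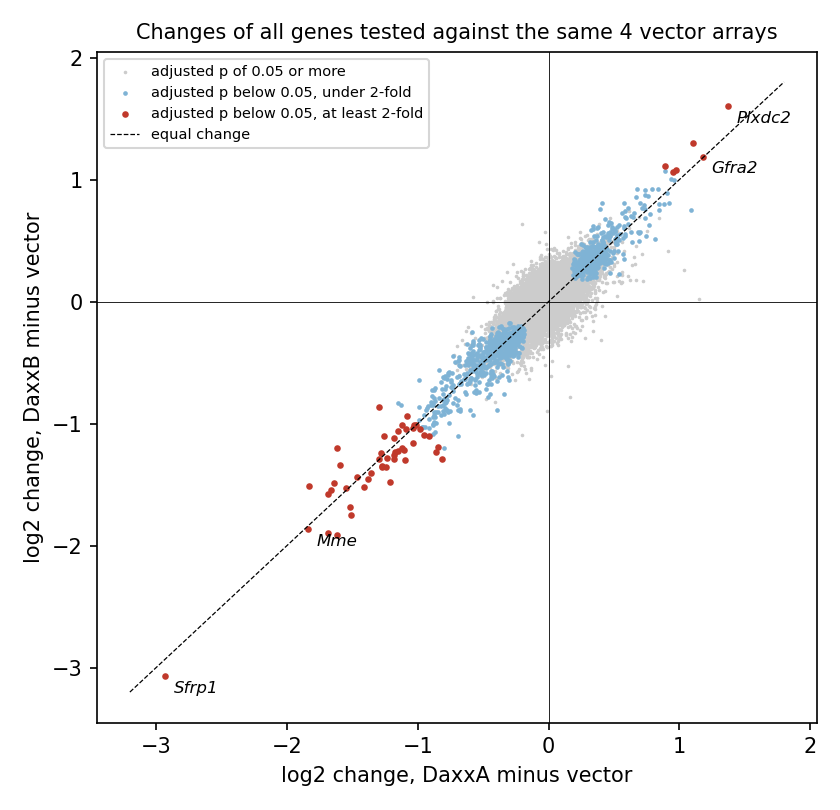
Each point is 1 gene, with its log2 change in DaxxA minus vector on the horizontal axis and in DaxxB minus vector on the vertical axis, both against the same 4 vector arrays. The 54 genes changed at least 2-fold (red) were selected on DaxxA and DaxxB together, which fixes a common sign, and run from Sfrp1 at -2.93 and -3.07 to Plxdc2 at 1.37 and 1.60.

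The difference between DaxxA and DaxxB was tested directly. In the fit of all 8 arrays 0 genes passed in limma, with 846 at an unadjusted p under 0.05. Without vector replicate 2, which belongs to neither group but enters the estimate of spread, 428 passed (157 higher in DaxxA and 271 higher in DaxxB) and 0 reached 2-fold. The median difference of all genes was -0.0361 in that fit, so the excess on the DaxxB side went with a small shift of all genes. Marker lists had medians from -0.126 (blood cells) to -0.0284 (pluripotency), apart from 0.054 for the sex chromosomes. There the highest values in DaxxA over DaxxB were those of the zinc finger genes Zfp975 (0.95 on the log2 scale, adjusted p = 0.013) and Zfp931 (0.89, adjusted p = 0.0237), of the long noncoding RNA gene Dleu2 (0.68), of Anp32-ps (0.58), a pseudogene whose signal may be shared with its parent genes, and of Fbxo28 (0.52), a ubiquitin ligase subunit. The lowest were Tex24 (-0.58), C2cd4b (-0.49), Cd1d2 (-0.48), a lipid-presenting molecule, Syna (-0.47), the fusogen syncytin A, and Foxn1 (-0.46), a transcription factor of thymic epithelium. Camera called 4 lists there with the preset correlation and 0 with an estimated one. Cell cycle genes were higher in DaxxA (adjusted p = 0.00935, or adjusted p = 0.418 with an estimated correlation), as were cholesterol genes (0.00935, or adjusted p = 0.486 with an estimated correlation). The list of 4 measured sex chromosome genes was also called higher (0.0365, or adjusted p = 0.418 with an estimated correlation). Its median was only 0.054, and Xist among them differed by 0.406. Collagens were lower (0.038, or adjusted p = 0.418 with an estimated correlation).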

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

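The tests of a compressed signal range and of a wrong label on vector replicate 2 were chosen after the result was seen, as were those of the smallest p of any list over splits.

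Vector replicate 2 lay far from the other vector arrays in interquartile range (2.79) and in mean correlation with the other arrays (0.969). Among the 25 genes of the plot of named genes it was also far from the other 3 vector arrays for Svep1 (8.86), Rasl11a (10.6), Plxdc2 (7.06), Nid1 (7.76) and Tnfaip2 (7.2). Vector replicate 1 stood apart for Tagln (7.25) and DaxxA replicate 2 for Parvb (8.92) among the 4 Daxx arrays. These 9 came from 54 groups of 4 values, of which chance marks about 1 in 20, and 7 of the 9 were in vector replicate 2.

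The position of vector replicate 2 was weighed against 3 explanations. A Daxx array with a vector label is argued against: on a scale from the other vector arrays (0) to the Daxx arrays (1), its median position over the 2558 genes called without it was 0.224, with quartiles at -0.416 and 0.825, and over the 62 genes changed at least 2-fold it was 0.166, with quartiles at 0.0857 and 0.255. Cells of another type stay open: 0 of 9 marker lists of other cell types reached the extreme upper end of 10000 level-matched random lists (highest percentile 85.39), but 6 of the 9 lay above the matched median, and staying under that end, the bound set in advance, does not exclude a small share of such cells. A compressed signal range of the array stays open: its deviation from the other vector arrays was 0.49 in the dimmest of 5 equal groups of genes and -0.11 in the brightest, a difference of 0.6, where the other vector arrays differed by at most 0.0259, and this may reflect RNA or hybridization quality, which no label records.

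Counts of called genes were set against other splits of the arrays. For Daxx against vector, 902 genes and 54 at 2-fold compared with 0 and 0 as the highest of the other splits, so that 1 of 35 splits, the real one, gave as many, and chance can be excluded if the arrays are independent, which the labels do not state. The same held on 7 arrays, with 2558 genes against a highest of 0 and 1 of 35 splits. There, however, arrays of a group were correlated at 0.211 in the fit with the group as a random block (-0.16 on 8 arrays). DaxxA and DaxxB also differed in 428 genes on 7 arrays, so independence of the arrays is in doubt. Such splits do not exclude a difference between the groups other than Daxx. For the number of gene lists chance cannot be excluded on 8 arrays, because 16 of 35 splits gave 11 or more and the highest was 18. On 7 arrays the real split gave 10 lists, 1 of 35 splits gave as many, and the highest other was 9. If the arrays are independent, chance can be excluded there by the share of splits, but only by a margin of 1 list and with the preset correlation.

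Taken by itself, the interferon list had its smallest camera p in the real split on 8 and on 7 arrays (1 of 35 splits each). Hox genes and fibroblast markers did so too. For the interferon list this decides nothing, because it was chosen as the most shifted of 35. The smallest p of any list was therefore compared over the splits. On 8 arrays it was 1.7e-12 unadjusted in the real split and 2.1e-07 as the smallest of the others. That is 1 of 35 splits, the smallest share they can give, so chance can be excluded only if the arrays are independent, which the labels do not state. On 7 arrays the smallest camera p was 1.09e-13 against 3.53e-12, again 1 of 35. Chance can be excluded there by the share of splits under the same condition, although 1 other division came close.

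DaxxA and DaxxB differed in 428 genes on 7 arrays by a test of the difference itself, and in 0 in limma on all 8, where 846 had an unadjusted p under 0.05. Among 13767 probe sets with several gene names or none, which enter no count above, 75 passed the threshold (35 higher, 40 lower), 6 of them at 2-fold, and all 75 were also called without vector replicate 2.

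The Daxx probe set did not separate the conditions. A signal no higher than nonspecific hybridization is argued against, because the vector mean lay above 99.2% of the olfactory receptor genes, and the lowest vector array still placed Daxx above 97.7% of them. Probes outside the deleted part of the gene, or outside the sequence put back, stay open as an untested explanation, as do low levels of the reintroduced transcript.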

How the results depend on the processing

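Added after the data were seen were the combined settings on 7 arrays, without vector replicate 2. The direction of the 86 named genes and 11 lists called was kept under every alternative run, with 0 reversed. Lists not called did turn without vector replicate 2, such as blood cell markers (median -0.0702 to 0.0656) and epithelial markers (-0.0408 to 0.0203). Of 86 named genes called, 36 were called under every alternative that tested them and 50 were lost under at least one. The count of 902 became 1402 with quantile normalization, 561 with median centring, 1533 with cyclic loess, 1442 among genes above the median level, 3232 with array weights and 1947 with the group as a random block. The corresponding values for DaxxA (393) were 659, 223, 759, 633 and 2720 with array weights, and for DaxxB (536) 1037, 257, 1127, 1051 and 4252, and 901 with a trended and robust prior. Genes changed the same way in both (316) numbered 523, 171, 589, 513 and 1914. DaxxA against DaxxB gave 485 with array weights and 0 as fitted first. The filter on level tests fewer genes. Array weights gave vector replicate 2 the lowest weight, 0.0521, and for the other settings the cause was not tested. On 7 arrays the fit of 3 groups gave 3461 and the random block 1528 for the count of 902. Lists called fell from 11 to 7 among genes above the median level and to 1 with an estimated correlation, on 8 and on 7 arrays. Fry in its form for one direction called 11, of which 8 were among the 11 of camera and the others were the Wnt, matrix protease and imprinted lists. Scaling moved the median change of all genes from -0.0281 to between -0.00392 and 0.00254, and the share of lower genes stayed between 59.1% and 62.7%.

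Leaving out single arrays gave 446 to 2558 genes for the count of 902, 49 to 62 at 2-fold, 71 to 2246 for DaxxA, 82 to 4083 for DaxxB, 0 to 428 for DaxxA against DaxxB, 71 to 1678 for both, 9 to 12 lists, and a Daxx difference of 0.10 to 0.26. The highest values were those without vector replicate 2, except for the lists (highest without vector replicate 4 or DaxxB replicate 2) and the Daxx difference, where that array gave the lowest. A lone DaxxA or DaxxB array is then assumed to vary like the other groups.

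The replicate numbers were not taken as pairs in the main fit, since DaxxA and DaxxB hold only 2 numbers each. Deviations of same-numbered arrays correlated at 0.0238 to 0.162, all above 0. They were not set beside those of differently numbered arrays, so a pairing by number stays open. With the replicate block the count was 162 genes, with 43 at 2-fold, and 0 for DaxxA, 0 for DaxxB and 0 for both, which leaves few degrees of freedom. No depth applies to arrays, and dim genes are compressed toward the background.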

Other observations

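The test of male cells, the neighbour pairs on 7 arrays, the families by symbol prefix and the choice of the genes named in the next paragraph were made after the result was seen.

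Beyond the 24 named genes, 36 others changed at least 2-fold, and all of them fell. Among the secreted signals were Fgf10, a fibroblast growth factor of limb and lung budding (-1.42 on the log2 scale), Cxcl12, a chemokine for haematopoietic cells (-1.38), Bmp4 (-1.19) and Bmp2 (-1.04), bone morphogenetic proteins, Igf1, an insulin-like growth factor (-1.10), and Pdgfd, a platelet-derived growth factor (-1.01). Regulators of transcription included Ppargc1a, a coactivator of mitochondrial genes (-1.32), Plag1, a zinc finger activator (-1.22), and Ebf3 (-1.19). Cgas, the cytosolic DNA sensor that makes cyclic GMP-AMP, fell by 1.04 (adjusted p = 0.00114), with changes of -0.86 in DaxxA and -1.23 in DaxxB. Abca1, a cholesterol exporter, fell by 1.03, and Sod3, an extracellular superoxide dismutase, by 1.11.

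Xist was lower in the Daxx arrays, with changes on 7 arrays of -0.72 in DaxxA and -1.13 in DaxxB, a difference of 0.41 (adjusted p = 0.0201). Male cells mixed into the Daxx arrays are argued against, because 3 Y-linked genes changed by 0.0462 on average (95% interval -0.02 to 0.11). The normalization of the arrays is argued against, since the smallest share of the change kept under quantile normalization, median centring and cyclic loess was 0.973. Loss of the inactive X chromosome in part of the cells stays open and is a hypothesis: 5 genes that escape X inactivation changed by -0.146 on 7 arrays (95% interval -0.24 to -0.05), but by -0.11 on 8 arrays with an interval from -0.22 to 0.0047, and Ddx3x, 1 of the 5, changed by 0.01 on 7 arrays. Lower transcription of Xist itself was not tested and may equally apply, and the Daxx condition stays among the open explanations.

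Called genes lay next to each other on the chromosomes, by the gene order of GRCm38.p6. There were 50 neighbouring pairs with different symbol prefixes called in the same direction (36 lower, 14 higher), against a mean of 18.2 in 10000 random reassignments of the calls (share 1e-04, the smallest they can give), and 23.4 when genes were reassigned among genes of like level. Without vector replicate 2 there were 321 pairs against a mean of 146, and of 186 among genes of like level. Examples are Cd34 and Plxna2, Grem1 and Fmn1, Osmr and Lifr, Tap1 and Psmb8, and Ppbp and Cxcl5, all lower. Related genes under different prefixes, such as the chemokines Ppbp and Cxcl5 and the cytokine receptors Osmr and Lifr, are among the pairs. So are microRNA genes with an adjacent gene, such as Mir218-1 with Slit2 and Mir196a-1 with Hoxb13, whose signals may overlap. Runs of genes such as Parp14, Dtx3l and Parp9 were counted pair by pair. Regional regulation of neighbouring genes is a candidate explanation, as is co-regulation of functionally related neighbours such as the antigen processing genes, which the data do not separate.

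Of 130 families of at least 15 genes that share a symbol prefix, camera called 9 on 8 arrays, 1 without vector replicate 2 and 0 with an estimated correlation. The 1 called in both was the Snora family of small nucleolar RNAs (20 genes, median 0.18, adjusted p = 8.66e-05; adjusted p = 0.993 with an estimated correlation; 0.00867 on 7 arrays). Olfactory receptor genes had a median of -0.10 on 8 arrays (adjusted p = 0.00428; adjusted p = 0.993 with an estimated correlation) and 0.02 without vector replicate 2 (adjusted p = 0.621).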
